A study of Mus musculus with 4 samples.

How the data were processed

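The measurements are 10x Genomics droplet RNA counts from cells of the proximal and distal tibia, released by dispase, collagenase and trypsin, per the labels' protocols. The 4 sample records carry the same genotype, age and treatment labels. The authors deposited 1 matrix of raw UMI counts per gene and barcode, written by Cell Ranger 3.1.0 per the file headers. The submitters' processing notes also name Cell Ranger 3.1.0, Seurat 3 and the mm10 build, and do not say what Seurat was used for. A second deposited matrix gives UMI counts of 98 added sequences (92 ERCC spike-ins and 6 transgene elements) over 6794880 barcodes. How these were aligned is not given in the sources used here. Of the 98, tdTomato, WPRE and EGFP had a UMI, and Cre, LacZ and IRES had 0. All barcodes carry 1 suffix, so the 4 records count as 1 library and leaving out records was not possible.

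Depth per barcode ranged from 500 to 80413 UMIs, with a median of 3812. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. This left out 1335 barcodes with few genes (median 66.2% mitochondrial UMIs) and 2672 with a higher mitochondrial share. Scrublet, as run in scanpy 1.11.5, marked 607 of the 11007 remaining barcodes (5.51%) as doublets, which were removed, leaving 10400 cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes gave 30 principal components, and 15 nearest neighbours were joined with shared-neighbour weights. Leiden clustering (leidenalg 0.10.2) was run at resolution 1.0 with seed 0. The added sequences took no part in clustering. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

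Markers of 23 cell types, 16 gene lists, the rule for named genes, the filters, the comparisons and most alternatives were fixed before the data were examined. The rule that turns markers into names was not: it was set, and revised several times, after the clusters had been seen. A marker counted as raised at 2 times the CPM of all other cells with a UMI in at least 10% of the cluster's cells. A cluster took the name of the type with the most raised markers, given at least 3. It stayed unnamed where another type had as many, or where another type had more markers, and at least 2, among its 10 leading genes. It also stayed unnamed where it shared 4 or more leading genes with a larger cluster of another name, or where it had a median depth below 0.333 of the library's and no own marker among the leading genes. These rules keep cluster 32 (24 cells, 0.231%) out of any class and keep cluster 8 (553 cells), which has the dendritic marker H2-Aa among its leading genes, in the B lineage. Cluster 21 tied between osteoblast and marrow stromal markers. An earlier form of the rule named it marrow stromal by breaking the tie, and that name was lost under several settings. It is described instead as the unnamed cluster with the highest Cxcl12 CPM, at least 50 times that of all other cells. That factor was raised from 10 after the results had been seen, because at the limit of 5% mitochondrial UMIs the factor of 10 picked a cluster of 41 cells. This cluster had 5 Cxcl12 UMIs, and its leading genes (Lpin2, Dyrk3, Ypel4) were examined only after the change. The factor of 10 was then run as an alternative, since the change removed 3 sign changes from the comparison of settings.

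Counts were summed per class and given as CPM with exact Poisson intervals, shares of cells with exact Clopper-Pearson intervals, and ratios with exact conditional binomial intervals, all at 95% and for counting error only. A count of 0 is given with the limit of 3 counts. Shares were also computed after thinning each cell to 1000 UMIs, leaving out shallower cells. For list members with at least 20 UMIs over both sides and outside the cell type markers, log2 ratios were taken with 0.5 counts added per side. List medians were placed among 10000 random lists drawn gene by gene from the 100 neighbours on each side in mean expression, and their intervals come from 1000 Poisson resamples. With 0.5 counts added, a rare gene with 0 UMIs in a small class can come out higher, so members called higher were counted only where the class had a UMI. This count leans on being seen, since 1 UMI in the osteoblast-like class is 2.84 CPM, and is given out of all measured members. This was found and changed after the lists had been seen, and lowers the Wnt count in osteoblast-like cells from 11 to 8. Where a list has members with 0 UMIs, its median is also given with these at the floor of 3 counts. By the rule for named genes, the text draws on the 2 highest and 2 lowest members of each list by log2 ratio, and on Irx3, Irx5, Pth1r and Col10a1. The rule's other part, the 10 highest and 10 lowest genes of each reporter comparison, found no comparison to apply to. The comparison of osteoblast-like cells with the Cxcl12-rich cluster, the count of both together and WPRE as a reporter were chosen after the data were seen. Alternatives covered resolution, mitochondrial and UMI limits, doublets, principal components, seed, thinning depth, reporter minimum and list members. The test of cluster 25 for epithelial cells first used only the share of barcodes with Hbb-bs, which argued against them; the level per UMI was added later. It was also lower within the same UMI range, but over all barcodes it overlaps that of neutrophil-like and B lineage-like cells, and this comparison leaves the explanation open. Genes named outside this rule, such as S100a8, Hbb-bs and the reporters, were chosen after their values were seen.

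On simulated counts with 200 of 13603 genes changed, the ratio intervals of osteoblast-like cells against the rest covered the true value for 97.0% of genes changed 2-fold and 97.0% of those changed 4-fold. They excluded no change for 68.0% and 89.0%. For the Cxcl12-rich cluster the coverage was 98.0% and 98.0%, and no change was excluded for 77.0% and 91.0%. Of 16 unchanged lists, 0 and 1 lay outside the central 95% of random lists. The simulated counts were Poisson draws from 1 pooled profile, so coverage near 95% follows from the design and spread between cells is not covered. The changed genes were picked among those with at least 1000 UMIs over both sides. The shares that excluded no change therefore do not hold for rarer genes, such as list members with 20 UMIs. Gene coordinates come from GENCODE release M21 on mm10, matched by Ensembl identifier for 30934 genes, 30468 of them under the same symbol. The planned comparison of tdTomato-positive with negative cells had too few cells and was not run.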

Results

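Single-cell RNA sequencing was done on cells released from the trabecular bone of the proximal and distal tibia of mice aged 8 weeks. The labels give 1 group of 4 sample records. Its genotype combines Col10a1-Cre, a Rosa26 tdTomato reporter and heterozygous alleles of Irx3 and Irx5, and its title says that no PTH (parathyroid hormone) was given. Col10a1-Cre acts in hypertrophic chondrocytes, the cartilage cells of the growth plate that precede bone, so the reporter marks these cells and their descendants. The deposited matrix pools the 4 records with 1 barcode suffix, so cells could not be tied to a record. The labels do not say whether the records are 4 animals or repeated sequencing of 1 library. All values below therefore come from 1 library without replicates, no test between animals was possible, and every interval is a 95% interval that covers counting error only. The matrix held 90273806 UMIs (unique molecular identifiers), and the median barcode had 3812 UMIs. After filtering, 10400 cells in 34 clusters remained, with a median of 4825 UMIs.

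The first comparison asked which cell types the suspension held. Blood lineages made up 94.1% of the kept cells (9783 cells, exact binomial interval 93.6% to 94.5%). B lineage-like cells were the largest class with 33.7% (3503 cells), followed by neutrophil-like cells with 26.7% (2781 cells) and erythroid-like cells with 15.4% (1602 cells). Monocyte or macrophage-like cells gave 8.09%, haematopoietic progenitor-like cells 4.96% and T or NK-like cells 2.92%. Osteoclast-like cells, the bone-resorbing cells of the myeloid lineage, numbered 34 (0.327%, interval 0.227% to 0.457%).

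Bone-forming cells were rare. The osteoblast-like class was 1 cluster of 14 cells, 0.135% of the total (interval 0.0736% to 0.226%), with a median of 24092 UMIs per cell. Its size depends on the settings: 120 cells at resolution 0.5, 195 and 74 at limits of 30% and 5% mitochondrial UMIs, and 53 with at least 1500 UMIs. A cluster of 118 cells (1.13%, interval 0.940% to 1.36%) had as many raised markers of osteoblasts as of marrow stromal cells, was left unnamed, and is called the Cxcl12-rich cluster here, after the chemokine that marrow stromal cells secrete. Its cells had a median of 2507.5 UMIs. Both together made up 1.27% of cells (132 cells, interval 1.06% to 1.503%). With at least 1500 UMIs per cell this share was 0.572%, and the osteoblast-like class then also took in cells of the Cxcl12-rich cluster. No cluster was named osteocyte, chondrocyte, hypertrophic chondrocyte, fibroblast, tenocyte, adipocyte, pericyte, endothelial, skeletal muscle, Schwann, megakaryocyte or marrow stromal, and 485 cells in 6 further clusters stayed unnamed. In the Cxcl12-rich cluster S100a8, a neutrophil gene, had a UMI in 85 of 118 cells (72.0%) and Hbb-bs, a haemoglobin gene, in 112 (94.9%), while Col1a1 had one in 38. B lineage-like cells had like shares (72.9% and 93.2%), so the shares are not particular to this cluster. In amount, S100a8 and Hbb-bs gave 12814 and 12674 of the cluster's 377987 UMIs. Their medians were 1 and 3 UMIs per cell, so part of the barcodes holds nearly all of these counts. The cluster's values below therefore also hold transcripts of blood cells.

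**Figure D1:**
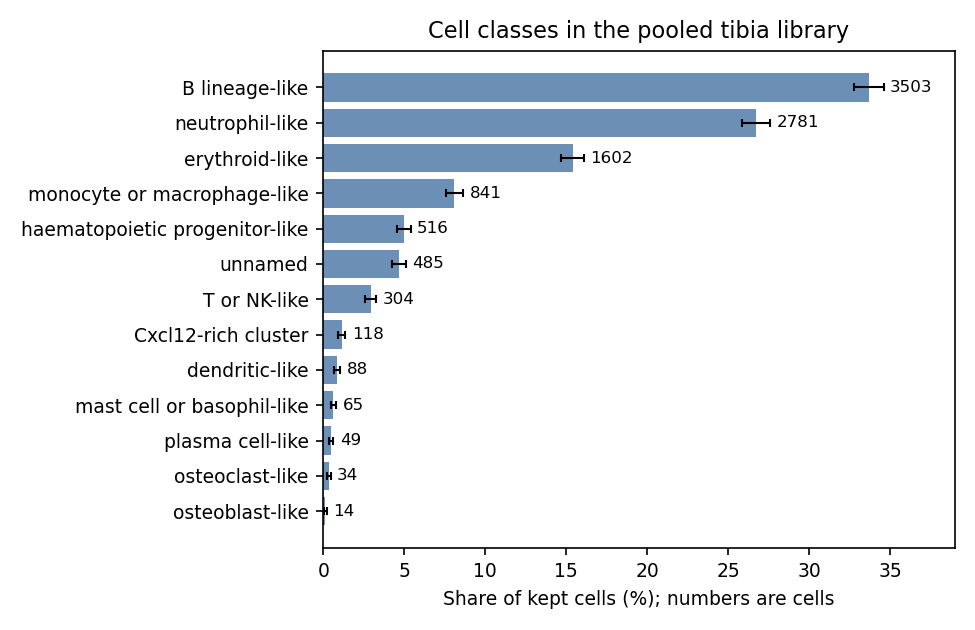
Share of the 10400 kept cells in each class, in percent, for the pooled tibia library. Bars give the share, whiskers the 95% exact binomial interval (counting error only), and the numbers the cells, from 3503 B lineage-like to 14 osteoblast-like cells.

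The second comparison asked where the tdTomato reporter was read. The tdTomato sequence itself gave few counts: 16 UMIs in the osteoblast-like cells (45.4 CPM, the field's depth-scaled count, exact Poisson interval 25.95 to 73.7), 3 in the Cxcl12-rich cluster and 43 in all blood classes together (0.633 CPM, interval 0.458 to 0.853). WPRE, a viral RNA element that common tdTomato cassettes carry behind the reading frame, was far more abundant, with 750 UMIs and 2128 CPM (interval 1979 to 2286) in osteoblast-like cells. It reached 476 CPM (interval 409 to 551) in the Cxcl12-rich cluster and 38.2 CPM (interval 36.8 to 39.7) in blood classes. The labels do not say which cassette the mice carry, and WPRE was taken as a reporter only after the counts had been seen.

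Per cell, tdTomato had a UMI in 6 of the 14 osteoblast-like cells (42.9%, median depth 24092 UMIs) and in 0.429% of blood cells (median depth 4998 UMIs), which should lack the Col10a1 lineage. After each cell was thinned to 1000 UMIs, 1 of 14 osteoblast-like cells (7.14%, interval 0.181% to 33.9%) and 0.0846% of blood cells (interval 0.0365% to 0.167%) kept one. WPRE had a UMI in all 14 osteoblast-like cells and in 19.7% of blood cells before thinning. After thinning the shares were 78.6% (11 of 14 cells, interval 49.2% to 95.3%) and 5.14% (interval 4.70% to 5.60%). In the Cxcl12-rich cluster WPRE was found in 46 of 118 cells, and in 16 of 80 cells after thinning (interval 11.9% to 30.4%), with 38 shallower cells left out. The thinned shares of the 14 cells rest on few counts: the tdTomato share was 0% after thinning to 500 or 2000 UMIs, and the WPRE share was 30.5% at resolution 0.5, where the class took in 106 cells of the Cxcl12-rich cluster.

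**Figure D2:**
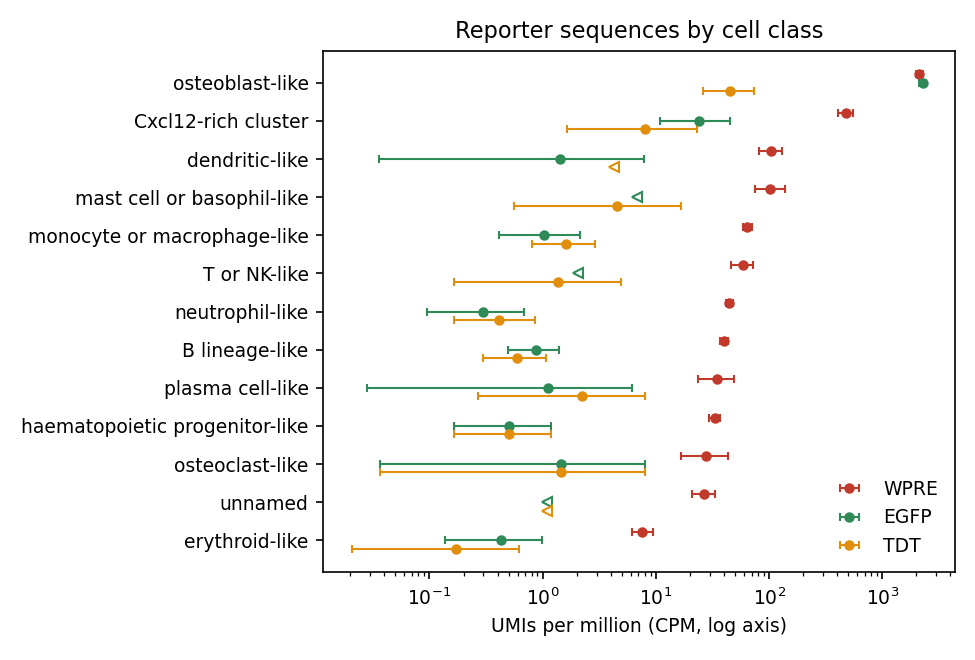
CPM (log axis) of WPRE, EGFP and tdTomato (TDT) in each cell class. Points are summed counts with 95% exact Poisson intervals, and open triangles mark the limit that 0 counts allow (3 counts). WPRE was highest in osteoblast-like cells at 2128 CPM and lowest in erythroid-like cells at 7.60 CPM.

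EGFP, which the labels do not name, had 800 UMIs in 7 of the 14 osteoblast-like cells and 41 UMIs in blood classes. The Cxcl12-rich cluster had 9 EGFP UMIs in 5 of its 118 cells (23.8 CPM, interval 10.9 to 45.2). WPRE counts per osteoblast-like cell ranged from 1 to 124 UMIs. The cell with 1 WPRE UMI also had 194 S100a8 UMIs and 60 Col1a1 UMIs, where the median osteoblast-like cell had 1283 Col1a1 UMIs.

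**Figure D3:**
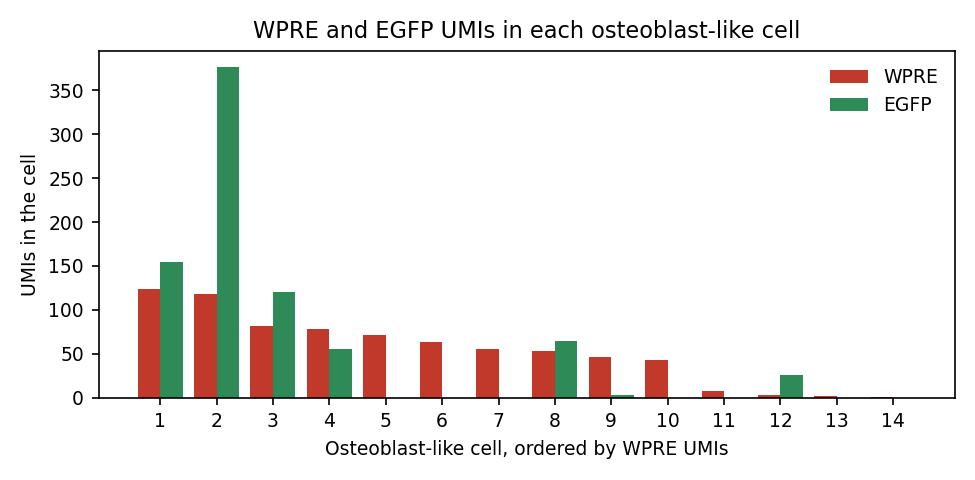
UMIs of WPRE and EGFP (linear axis) in each of the 14 osteoblast-like cells, ordered by WPRE UMIs. Bars are counts per cell; cells 5, 6, 7 and 10 have 43 to 72 WPRE UMIs and 0 EGFP UMIs.

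The design also planned to compare tdTomato-positive with tdTomato-negative cells within each skeletal class. At least 50 cells on each side were required beforehand. The osteoblast-like class held 14 cells in all. The Cxcl12-rich cluster held 3 tdTomato-positive cells, and by WPRE 46 positive and 72 negative cells before thinning and 16 against 64 after it. This comparison and its gene lists were therefore not run.

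The third comparison followed Irx3, Irx5 and Pth1r, the genes named by genotype and treatment. Pth1r, the receptor of parathyroid hormone, lies on chromosome 9 from 110722085 to 110747145 (mm10). It had 188 UMIs and 534 CPM (interval 460 to 615) in osteoblast-like cells, 71.4 CPM (interval 47.1 to 104) in the Cxcl12-rich cluster and 0.604 CPM (interval 0.433 to 0.819) in blood classes. All 14 osteoblast-like cells had a Pth1r UMI, against 0.409% of blood cells. After thinning the shares were 42.9% (6 of 14 cells, interval 17.7% to 71.1%) and 0.137% (interval 0.0732% to 0.235%), and the Cxcl12-rich cluster had 6.25% (interval 2.06% to 14.0%).

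Irx3 and Irx5 encode Iroquois homeodomain transcription factors and are protein-coding genes on chromosome 8, Irx3 from 91798525 to 91802067 and Irx5 from 92357625 to 92376286. Irx5 had 26 UMIs in osteoblast-like cells (73.8 CPM, interval 48.2 to 108), 2 in the Cxcl12-rich cluster and 6 in blood classes (0.0883 CPM, interval 0.0324 to 0.192). Irx3 had 13 UMIs in osteoblast-like cells (36.9 CPM, interval 19.6 to 63.1), 3 in the Cxcl12-rich cluster and 5 in blood classes (0.0736 CPM, interval 0.0239 to 0.172). A UMI of Irx5 was present in 9 and of Irx3 in 5 of the 14 cells, and after thinning in 2 and 0 cells, so thinning to this depth hides Irx3 and sets no bound on its share. At resolution 0.5, where the class took in 106 cells of the Cxcl12-rich cluster, the thinned Pth1r share was 13.4%. In blood cells the unthinned shares were 0.0613% and 0.0511%, and the thinned shares 0.0106% and 0.0211%. All records are labelled heterozygous, so these levels have no wild-type counterpart here. Col10a1, on chromosome 10 from 34389981 to 34397085, had 0 UMIs in osteoblast-like cells, which allows up to 8.51 CPM, 0 in the Cxcl12-rich cluster and 6 in blood classes.

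**Figure D4:**
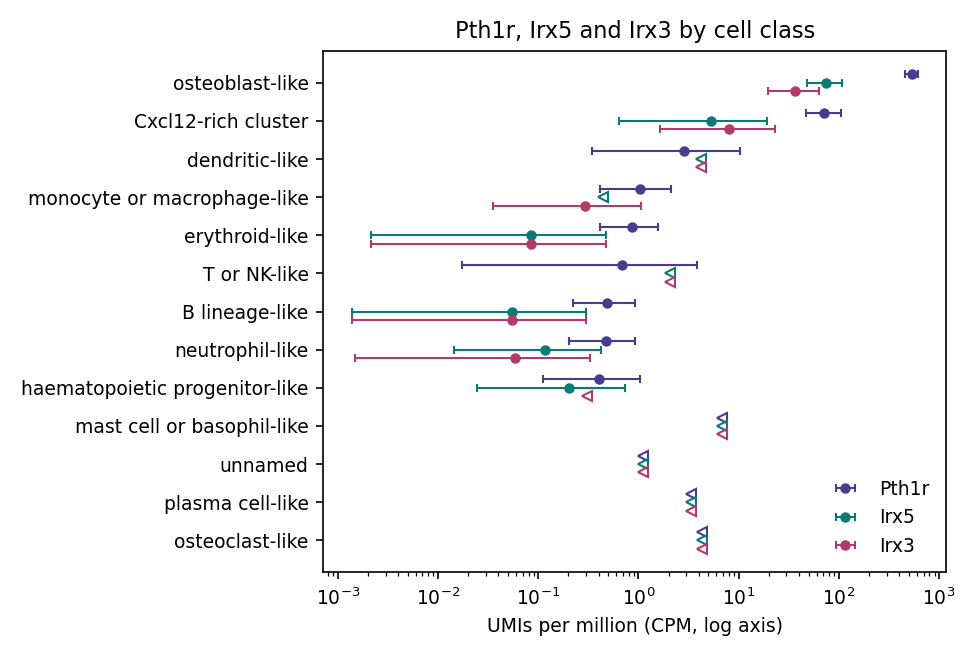
CPM (log axis) of Pth1r, Irx5 and Irx3 in each cell class, with 95% exact Poisson intervals; open triangles mark the limit that 0 counts allow (3 counts). Osteoblast-like cells had 534, 73.8 and 36.9 CPM.

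The fourth comparison described the skeletal clusters with gene lists that had not named them. List genes were not left out of the clustering, so list medians are not independent of how the clusters were formed. Col1a2, Sparc, Col5a2 and Serpinf1 of the bone matrix list and Col11a1 of the cartilage list were among the 10 leading genes of the osteoblast-like cluster. In osteoblast-like cells against all other kept cells, 14 of 16 measured members of the bone matrix and mineralisation list were at least 1.5 times higher. Its median log2 ratio was 9.12 (counting interval 8.80 to 9.46), at percentile 100 of 10000 random lists matched on mean expression. Cthrc1 had 551 against 0.239 CPM, and Col1a2, a chain of type I collagen, 71140 against 37.6 CPM. Atf4 (434 against 391 CPM) and Ank (17.0 against 21.2 CPM) lay within 1.5 times. All 10 matrix proteases and inhibitors were higher (median 7.57, interval 7.15 to 7.97), among them Mmp2 with 516 against 0.366 CPM and Mmp16 with 179 against 0.113 CPM. The class also had 4 raised chondrocyte markers (Sox9, Col2a1, Comp and Hapln1), which as markers stay outside the cartilage list's median. A UMI in 10% of cells was enough for this, so these markers may rest on few of the 14 cells. The class was uneven: the osteoblast marker Bglap had 4, 4 and 7 UMIs in cells 5, 10 and 14, and 5415 in cell 1. Of the 3 cartilage list members measured, Col11a1, a fibrillar collagen, had 3613 against 2.17 CPM. Sox6, a transcription factor, was lower with 3 UMIs (8.51 against 48.7 CPM, 0.204-fold, interval 0.0361 to 0.512). The other kept cells are mostly blood and hold no chondrocyte class, so the Sox6 ratio does not compare with cartilage.

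The medians of 3 signalling lists lay above 0 in osteoblast-like cells, with single members lower. Of 13 Wnt pathway members, 8 were higher, among them the inhibitor Wif1 (136 against 0.718 CPM, 190-fold, interval 125 to 287) and Wnt4 (73.8 against 1.21 CPM). The other 5 had 0 UMIs, among them the transcription factor Lef1 against 48.2 CPM elsewhere. Lef1 was a leading gene of the B lineage-like cluster 14. A single UMI in the 14 cells is 2.84 CPM, so a rare gene comes out higher once it is seen at all. The list's median was 2.10, also with its 5 unseen members placed lowest, and 3.54 with these at the floor of 3 counts. In the BMP and TGF-beta list 9 of 13 members were higher (median 2.47, interval 0.94 to 2.90), with Bmp2 at 93.7 against 0.831 CPM and Smad6 at 59.6 against 0.465 CPM, while Tgfbi was lower. In the Hedgehog and Notch list 5 of 10 members were higher, and Notch1 was lower with 2 UMIs against 51.3 CPM. Its median was 1.13, 0.49 with the 3 unseen members lowest and 2.33 with these at the floor. Both measured Iroquois genes were higher (median 8.81). Of the 7 skeletal stem and progenitor genes 4 were higher (median 1.66, and 1.63 with the unseen member at the floor), led by Prrx1 with 133 against 0.366 CPM. Immediate-early and heat-shock genes of the dissociation stress list, which tissue digestion can raise, were higher for 11 of 17 members (median 1.13, interval 1.02 to 1.32), with Fosb at 971 against 33.8 CPM.

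The medians of the cell cycle, interferon response and adipogenic lists lay below 0 in osteoblast-like cells. The other kept cells are mostly blood cells, so these medians set the class against blood. All 16 cell cycle genes were lower (median -3.08, interval -3.60 to -2.69, percentile 0), for example Top2a with 128 against 467 CPM. Of 10 interferon response genes 8 were lower, 3 of these with 0 UMIs, and the median was -1.62, -2.07 with unseen members at the floor and -3.59 with these lowest. Ifi27l2a had 3 UMIs against 188 CPM elsewhere. The adipogenic list had 7 of 11 members lower, 1 of these with 0 UMIs (median -1.65, and -1.74 with the unseen member at the floor). Fabp4, a fatty acid carrier, was 32.1-fold higher (interval 24.9 to 40.5), and Pparg had 2 UMIs (3.98-fold, interval 0.383 to 11.8). Lpl, Adipoq and Lepr, as cell type markers, stay outside this median, so it does not describe fat-cell genes as a whole. In the PTH and cAMP list 10 of 16 members were lower (median -0.77, percentile 14.7), including Rgs2 with 25.5 against 251 CPM, while Gnas, the stimulatory G protein subunit, had 1135 against 375 CPM. Pth1r, itself a cell type marker, stays outside this list's counts and median. It had 534 CPM in osteoblast-like cells against 0.604 CPM in blood classes. The medians of the niche factor (-0.19), hypoxia and glycolysis (-0.52), osteoclast regulator (-0.56) and cartilage (0.02) lists lay between percentiles 29.8 and 61.4. With unseen members at the floor they were -0.01, -0.59, 0.52 and 2.61. With these lowest, niche factor was -0.45, hypoxia -0.52 and cartilage -2.29, so the sign for cartilage depends on its 1 unseen member, and the osteoclast regulator median is not defined. The PTH and cAMP, adipogenic, hypoxia and osteoclast regulator medians turned above 0 at the limit of 5% mitochondrial UMIs, where the osteoblast-like class held 74 cells, 4 of them among the 14 cells and 41 from the Cxcl12-rich cluster. Leaving out the 50 most abundant genes adds 0.67 to the log2 ratio of every remaining gene in the class. The hypoxia and osteoclast regulator medians lie above 0 by this constant alone, which says nothing about these lists relative to other genes.

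**Figure D5:**
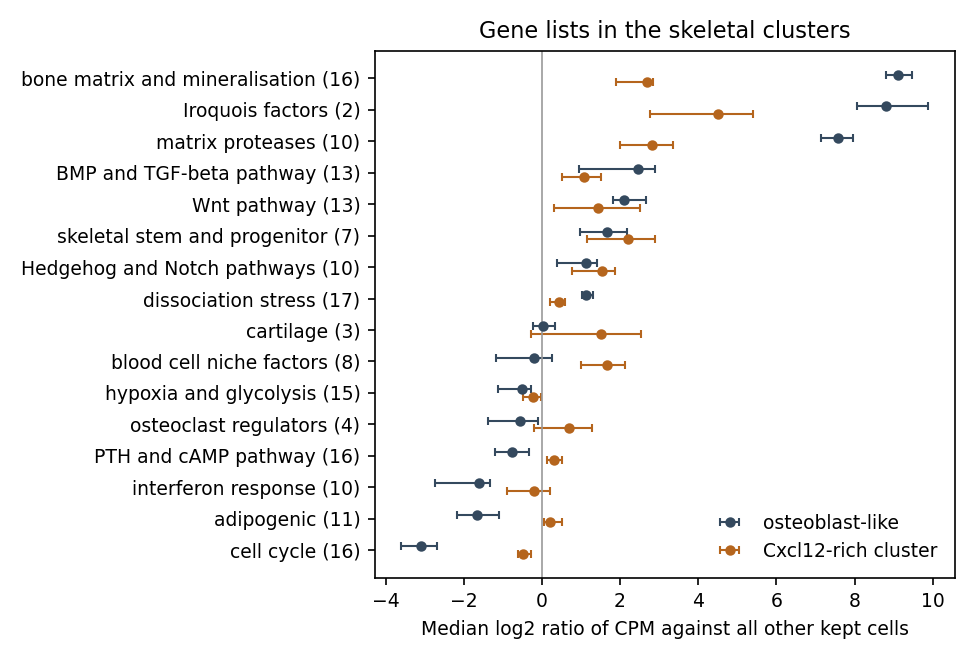
Median log2 ratio of CPM for each gene list in osteoblast-like cells and in the Cxcl12-rich cluster, each against all other kept cells. Whiskers are 95% intervals from resampled counts (counting error only), and numbers in brackets are measured members. The bone matrix list stood at 9.12 and 2.70.

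In the Cxcl12-rich cluster bone matrix and protease genes were also higher, at smaller ratios. The summed counts may rest on part of its 118 cells. Col1a1 had a UMI in 38 of them, Ibsp in 35, Adipoq in 31 and Bglap in 25, each with a median of 0, and Cxcl12 in 72. Whether these are the same cells was not tested, so the ratios below need not describe 1 kind of cell. Of its bone matrix genes 13 of 16 were higher than in all other kept cells (median 2.70, interval 1.91 to 2.85), and all 10 matrix proteases and inhibitors (median 2.82, interval 2.00 to 3.35). Factors that support blood cells were higher for 7 of 8 members (median 1.68, interval 0.99 to 2.14, percentile 99.95), among them the growth factor Igf1 with 87.3 against 5.01 CPM and Bmp4 with 23.8 against 1.61 CPM. The skeletal stem and progenitor list had 5 of 7 members higher (median 2.20), with Pdgfrb at 26.5 against 1.20 CPM. Wnt (8 of 13 higher, median 1.43, and 1.88 with the unseen member at the floor), Hedgehog and Notch (7 of 10 higher with UMIs present, median 1.54, 1.10 with the 2 unseen members lowest and 1.79 with these at the floor) and BMP and TGF-beta genes (9 of 13 higher, median 1.07) followed. Fabp4 was 53.8-fold (interval 43.8 to 65.4) and Pparg, the adipocyte transcription factor, 14.9-fold higher (interval 6.34 to 27.9), while the adipogenic median was 0.22. The remaining medians were 4.50 for Iroquois (percentile 98.95), 1.52 for cartilage (98.68), 0.70 for osteoclast regulator (61.39) and 0.43 for stress genes (98.98). They were 0.30 for PTH and cAMP (82.05, without Pth1r), -0.21 for interferon (2.58), -0.23 for hypoxia (0.555) and -0.49 for cell cycle genes (0). Matched random lists had medians above 0 here, from 0.10 for stress to 0.85 for Iroquois, so 0 does not mark no change. The osteoclast regulator and PTH and cAMP lists lay within the range of random lists. With unseen members at the floor the osteoclast regulator, stress and interferon medians were 1.28, 0.42 and -0.21.

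Set directly against the Cxcl12-rich cluster, a comparison chosen after the data were seen, osteoblast-like cells had 12 of 13 bone matrix genes higher (median 4.44, interval 4.25 to 4.83). Serpinf1 had 3278 against 95.2 CPM. The adipogenic list had 7 of 8 members lower (median -1.90, interval -2.45 to -1.30), with Apoe, a lipoprotein, at 53.9 against 320 CPM. Igf1 had 0 UMIs in osteoblast-like cells against 33 in the Cxcl12-rich cluster, and Vcam1, an adhesion molecule, 4 against 46. Cell cycle genes were lower for 15 of 16 members (median -2.72) and matrix proteases and inhibitors higher for 7 of 8 (median 3.90). The other medians were 5.11 for cartilage (1 member), 3.51 for Iroquois (1 member), 2.38 for skeletal stem and progenitor, 1.70 for Wnt, 0.92 for stress, 0.59 for BMP and TGF-beta, -0.27 for Hedgehog and Notch, -0.68 for hypoxia, -1.05 for PTH and cAMP, -3.27 for niche factor (-3.36 with the unseen member at the floor) and -3.91 for interferon genes (-3.44). Matched random lists had medians below 0 for Hedgehog and Notch (-0.58), hypoxia (-0.50) and PTH and cAMP genes (-0.43). These 3 lists lay at percentiles 64.1, 35.5 and 7.32, so the first 2 were not lower than other genes. Pth1r again stays outside the PTH and cAMP median. No osteoclast regulator reached the count minimum.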

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

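All tests in this part were chosen after the results were seen.

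EGFP, a sequence the labels do not name and outside the planned measurements, was read in osteoblast-like cells at 2270 CPM (800 UMIs). The Cxcl12-rich cluster had 23.8 CPM (9 UMIs) and blood classes 0.604 CPM. EGFP was present in 7 of the 14 osteoblast-like cells, with up to 376 UMIs in 1 cell. Free RNA would put EGFP in blood cells at a level of the same order and in every osteoblast-like cell, but the blood level was 0.0266% of the osteoblast-like level (interval 0.0189% to 0.0364%), and 7 osteoblast-like cells had none. Reads of the tdTomato cassette counted as EGFP would give both in every cell with many WPRE counts, yet 4 of the 10 cells with over 40 WPRE UMIs had 0 EGFP UMIs against 234 WPRE UMIs. Animals of different genotype may account for the pattern of 7 positive cells, if animals were pooled at all, although the 4 records carry the same genotype label. The labels do not say whether the 4 records are animals or repeated sequencing of 1 library, and the barcodes carry 1 suffix, so this stays open. No biological explanation was tested, since the labels give 1 group.

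Barcodes left out for their mitochondrial share held signal that the comparisons did not use. The 2672 barcodes held 718 WPRE UMIs, 4448 Col1a1 UMIs and 73 EGFP UMIs, the last in 19 barcodes.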

How the results depend on the processing

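The alternatives with at most 30% mitochondrial UMIs, WPRE in place of tdTomato, CPM without the 50 most abundant genes, resolution 0.5 for the gene lists, and the Cxcl12 factor of 10 were chosen after seeing the data. Of 336 alternative values, 198 stayed within the counting interval of the reported value, 126 moved outside it and 12 list medians whose reported interval excluded 0 changed sign. Among the 198 and 126, 7 of the 160 list values also changed sign, from medians whose interval included 0: 5 for niche factor and 1 for cartilage genes in osteoblast-like cells, and 1 for interferon genes in the Cxcl12-rich cluster. Of the 336 values, 87 were shares of single classes among the kept cells, and 51 of these stayed within the interval. The osteoblast-like class of 14 cells took in cells of the Cxcl12-rich cluster at resolution 0.5 (106 of 120 cells), at 30% and 5% mitochondrial UMIs (98 of 195 and 41 of 74) and at 1500 UMIs (36 of 53). At 30%, 83 of the 195 were in neither cluster, 78 of them left out by the filters of the reported setting. At 5%, 29 of the 74 were in neither, and 4 of the 14 cells were kept. The cause of the other shifts was not tested. No paired analysis was possible because the 4 records form 1 library.

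The share of osteoblast-like and Cxcl12-rich cells, 1.27%, was 0.572% with at least 1500 UMIs, 1.56% at 30% mitochondrial UMIs, 1.52% with doublets kept, 1.64% at resolution 2.0 and 1.97% with the Cxcl12 factor of 10 at 5% mitochondrial UMIs. The tdTomato share of osteoblast-like cells, 7.14%, was 42.9% without thinning, 78.6% with WPRE in its place, and 0% with at least 2 UMIs, thinned to 500 or 2000 UMIs, or with doublets kept. The WPRE share, 78.6%, was 100% without thinning, 42.9% thinned to 500 UMIs, 35.8% with at least 1500 UMIs, 30.5% at resolution 0.5, and 36.3% and 21.4% at 30% and 5% mitochondrial UMIs. The Pth1r share, 42.9%, was 100% without thinning and 13.4% at resolution 0.5. The bone matrix median, 9.12, was 8.07 and 8.58 at 30% and 5% mitochondrial UMIs and 8.37 at resolution 0.5.

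In osteoblast-like cells at most 5% mitochondrial UMIs turned the medians of the PTH and cAMP (0.23), adipogenic (0.0809), hypoxia (0.0301) and osteoclast regulator (0.0375) lists above 0. The osteoclast regulator median was also 0.49 at 30% mitochondrial UMIs, 0.0562 at resolution 0.5 and 0.11 without the 50 most abundant genes, where the hypoxia median was 0.15. Without the 50 most abundant genes, these 2 sign changes follow from a constant of 0.67 added to every remaining gene and do not test the lists. In the Cxcl12-rich cluster the adipogenic median was -0.18 with doublets kept. With the Cxcl12 factor of 10 at 5% mitochondrial UMIs another cluster of 41 cells took its place, and the PTH and cAMP (-0.90), adipogenic (-0.43) and stress (-1.37) medians were below 0. Not run were the alternatives of the comparison of tdTomato-positive with negative cells, which had too few cells, and leaving out each record.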

Other observations

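All tests in this part were chosen after the results were seen; the gene lists themselves were fixed before the data were examined.

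Genes that act on bone and marrow differed between classes, against all other kept cells. Mast cell or basophil-like cells (65 cells) had 421 CPM of the cytokine Il6 against 1.11 (376-fold, interval 289 to 498) and 277 CPM of Csf1, the macrophage growth factor, against 8.96, while Vcam1 was 0.101-fold (interval 0.00981 to 0.293) and Ccl2 had 0 UMIs against 16.1 CPM. Neutrophil-like cells, a far larger class, held 427 of the 757 Csf1 UMIs (25.2 CPM). Angpt1, a ligand of the Tie2 receptor, was 15.4-fold higher in mast cell or basophil-like cells (interval 10.7 to 21.1), while haematopoietic progenitor-like cells held 347 of its 466 UMIs (35.2 CPM). Kitl, the ligand of the Kit receptor, had 39 of its 100 UMIs in the Cxcl12-rich cluster (103 CPM). Tnfsf11, which encodes the osteoclast factor RANKL, had 47 of 106 UMIs in haematopoietic progenitor-like cells (4.77 CPM, interval 3.51 to 6.34). Its level was 10.6 CPM in the Cxcl12-rich cluster (4 UMIs, interval 2.88 to 27.1) and 2.84 CPM in osteoblast-like cells (1 UMI, interval 0.0718 to 15.8), so the counts do not rank these.

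T or NK-like cells had 11 of 16 PTH and cAMP list members higher (median log2 ratio 1.09, percentile 99.95), led by the nuclear receptors Nr4a3 (17.9-fold, interval 16.4 to 19.6) and Nr4a2 (13.4-fold, interval 12.3 to 14.6) and by Crem (10.9-fold, interval 10.1 to 11.7), while Hdac5 was 0.441-fold. Monocyte or macrophage-like cells had 14 of 17 dissociation stress genes higher (median 1.77), with Atf3 11.7-fold higher. Their interferon response genes were higher for 7 of 10 members and their adipogenic genes for 6 of 11, with Apoe 29.8-fold and Pparg 27.1-fold higher, while Rsad2 (0.343-fold, interval 0.307 to 0.381), Acsl1 (0.245-fold) and Dgat2 (0.228-fold) were lower. Neutrophil-like cells had 8 of 15 hypoxia and glycolysis genes higher, among them the glycolytic enzymes Pkm (2.83-fold) and Ldha (2.46-fold), with a list median of 0.66, while Pdk1 (0.151-fold, interval 0.102 to 0.209), Ankrd37 (0.419-fold) and Egln3 (0.575-fold) were lower. Haematopoietic progenitor-like cells had 8 of 10 interferon response genes lower (median -2.83, percentile 0).

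WPRE was read in every blood class, although blood should lack the Col10a1 lineage. Free RNA from osteoblast-like cells would keep WPRE and Col1a1 in 1 ratio, but WPRE per Col1a1 UMI was 58.5 times higher in blood classes (interval 53.9 to 63.6). Col1a1 per cell was also alike in erythroid-like and monocyte or macrophage-like cells (0.160 and 0.175 UMIs) where WPRE was not (0.0556 and 0.518). The ratio covers only the 14 kept osteoblast-like cells as a source, with 3.03 WPRE UMIs per 100 Col1a1 UMIs. The Cxcl12-rich cluster had 19.7 and blood classes had 177. Of 5900 WPRE UMIs, 1272 lay outside cell barcodes, so free WPRE RNA from other sources was not excluded. Reads of another transcript counted as WPRE cannot be told apart from low reporter expression, since tdTomato per WPRE UMI in blood was 0.776 of that in osteoblast-like cells with an interval of 0.429 to 1.48. Low activity of the reporter locus in blood also stays open. WPRE in erythroid-like cells was 0.170 of that in other blood classes (interval 0.136 to 0.211). The Rosa26 transcript Gt(ROSA)26Sor was 0.157 of it (interval 0.0317 to 0.472), resting on 3 against 92 UMIs. Both are ratios of CPM, and Hbb-bs alone gave 276432 CPM in erythroid-like cells, which lowers the CPM of other genes there. Low ratios of both therefore cannot show locus activity.

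Cluster 25 (80 cells, median 595 UMIs), unnamed, expressed epithelial genes: 18 of 22 on a list written after the cluster was seen were higher, with Krt13 at 9495 and Krt6a at 5671 CPM, against 0.0280 and 0.0140 elsewhere. A single UMI in the cluster is 18.5 CPM, so each listed gene seen at all came out higher, and the count says only which were seen. Cells of an epithelium in the same suspension would carry its free RNA, but Hbb-bs had a UMI in 53.8% of the cluster's barcodes (interval 42.2% to 65.0%), against 93.2% in the lowest non-erythroid blood class of over 50 cells, which is deeper. Within the same UMI range, with medians of 588.5 and 661.5 UMIs, the cluster was below blood barcodes in the share (48.6%, interval 36.7% to 60.7%, against 75.6%, interval 70.0% to 80.6%) and per UMI (1708 CPM, interval 1348 to 2134, against 3525, interval 3258 to 3808). These blood barcodes can include monocyte or macrophage-like cells, which had 12664 CPM of Hbb-bs over all depths, so the gap need not be one of free RNA. What also keeps the explanation open is the level over all the cluster's barcodes, 1829 CPM (99 UMIs, interval 1486 to 2227). It overlaps that of the deeper neutrophil-like (1675 CPM) and B lineage-like cells (1777 CPM), while the other such classes had 3777 to 12664 CPM. S100a8 also went both ways. Over all barcodes it had 831 CPM (interval 606 to 1112), above B lineage-like cells (449 CPM), while other such classes had 610 to 110178 CPM. Within the same UMI range it was lower in the share (44.4% against 66.7%) and per UMI (821 against 22625 CPM), with neutrophil-like cells not left out of the blood barcodes. Barcodes carried over from another library could account for the keratin counts, but under 5% of them were then predicted to hold Hbb-bs. The 48.6% within the same UMI range lay above this limit and below the share of the blood barcodes. Neither explanation's prediction for the share was met, so both stay open, and no biological explanation was tested.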
